A study of Mus musculus with 2 samples.

How the data were processed

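ATAC-seq libraries were made by Nextera tagmentation from midbrain of B6NCrl mouse embryos at embryonic day 13.5, with fragments of 200 to 750 bp, per the labels. The labels give 2 libraries of 1 group, numbered as biological replicates 1 and 2 and made from separate biosamples of pooled male and female embryos. The deposited files are 12 peak lists without header lines, 6 from the reads of both libraries pooled and 3 from each library, and text lists of files that were read for provenance only. Reads were aligned to the mouse genome mm10 and peaks were called, per the deposited file lists. The aligner, the peak caller, their versions and any shift of read ends for the transposase are not given in the sources used here. The peak lists hold no read totals, so depth per library is unknown, and no interval that needs it is given.

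The authors deposited peaks in the narrowPeak layout, and the unit of each column was read from its values. The deposited fold enrichment of a peak is a ratio of its signal over the caller's background, and it is not scaled between lists. The deposited -log10 p of a peak comes from the caller, and every listed peak had a p of at most 0.01. The deposited score is a whole number of at most 1000, and the ranked lists add scores that are the -log10 of the local and global irreproducible discovery rate (IDR). The authors' thresholded lists were tested against the ranked lists and held only peaks with an IDR of at most 0.05, on chromosomes 1 to 19, X and Y. The lists named pseudoreplicated, replicated and conservative were used under the names the depositors gave them. The 16 columns left unused hold the caller's -log10 q and the values of each compared peak set.

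Choices of tests, gene lists, patterns and alternatives were made before the data were examined, except where stated. Peaks of a list that overlapped were merged, since 1 interval can be listed once per summit, and a region took the highest fold enrichment and -log10 p of its peaks. The main list was the pooled list named replicated. Each library's own pseudoreplicated list served for comparing the libraries. Protein-coding genes and transcript starts came from the basic set of GENCODE M21, with 21851 genes and 41438 starts, and sequence from the GRCm38 reference assembly. A region that overlapped the 1000 bp on either side of a start was a promoter region, and every other region was distal. Distal regions were placed in exons, introns or intergenic sequence by their strongest summit. Coordinates are 1-based.

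A region was shared when at least 1 bp of it overlapped a region of the other library, and chance was measured with 100 random circular shifts within each chromosome. Errors of overlap shares are standard deviations over the 2 libraries' values, which count the same pair from each side. With 1 group there was no comparison between groups of samples. The share of genes with a promoter region was compared for 23 gene lists by Fisher's exact test, two-sided, against all other protein-coding genes. For distal regions, each was assigned to the nearest start within 100 kb, and the mean per gene was compared with 10000 random lists matched on the decile of territory length. The territory is the sequence nearest to a gene's starts. Benjamini-Hochberg adjustment covered the 23 lists of each test, with a threshold of 0.05, and the smallest two-sided permutation p was 0.0002. All members of the lists were found except Ahsp, which leaves 15 erythroid genes.

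For 21 sequence patterns, matches within 100 bp of the strongest summit were compared with flanks of 100 bp centred 500 bp away, with 0.5 added to both counts. A pattern was called when its ratio exceeded those of all of up to 50 letter permutations and its adjusted Fisher test of regions with a match passed the threshold. Sequence similarity was searched with blastn, with 90% identity over 100 bp and an E-value of 1e-10. CpG content was the observed over expected ratio within 500 bp of a start.

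Genes were named by a rule. It took up to 3 members per list with a promoter region in both libraries and the most distal regions, up to 2 members in alphabetical order without a promoter region in either library, and the 10 genes with the most distal regions. It added the genes nearest to the 10 regions of highest fold enrichment, 17 landmark genes, and up to 5 members per list with a promoter region in 1 library only. The alternatives were stricter and looser lists of the depositors, each library alone, other overlap rules, promoter windows of 500 bp and 2 kb, assignment within 50 and 500 kb, unmerged peaks, no matching on territory, matching on promoter CpG content, and other motif windows. Analyses of 22 gene families, of promoter strength and of pairs of lists were added after the data were seen.

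The procedures were tested on simulated data. For the overlap of libraries, 79.6% of 30000 simulated regions were given a copy and 80.1% were found shared. For promoter shares, lists planted at 98% were called in 89.2% of 250 cases, lists planted at 25% in 76.8% of 250, and unplanted lists in 2.33% of 600. Every unplanted gene had the same simulated chance of a promoter region, 66%. In the data the share of genes with one ran from 6.82% in the lowest decile of CpG content to 99.1% in the highest. The percentages of calls for promoter shares therefore do not cover lists that differ from other genes in CpG content. For distal regions, lists planted at 2 times the rate were called in 52% of 100 cases and unplanted lists in 0.714% of 280. The simulated mean rate was constant within a decile of territory length, so these percentages do not cover differences of territory within a decile. For patterns, 8 of 8 planted patterns and 0 of 76 unplanted ones were called. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and blastn 2.17.0.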

Results

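Chromatin accessibility was profiled by ATAC-seq, an assay in which a transposase tags open DNA, in midbrain from B6NCrl mouse embryos at embryonic day 13.5. The embryonic midbrain gives rise to the tectum and to the dopaminergic neurons of the substantia nigra. The series held 1 group of 2 libraries, each from its own biosample of pooled male and female embryos and labelled as biological replicates 1 and 2. With no other tissue, age or treatment, the comparisons were between the 2 libraries, between classes of regions, and between gene lists fixed in advance and the remaining genes. The files used here give no read totals, so the depth of each library is unknown. Peaks that overlapped were merged into regions, which gave 59730 regions covering 41.4 Mb in library 1 and 57742 covering 41.3 Mb in library 2. The pooled reads of both libraries gave a list that the depositors named replicated. It held 169529 peaks, merged into 79912 regions of median width 576 bp that covered 55.8 Mb, or 2.05% of chromosomes 1 to 19, X and Y. Regions and genes are not independent replicates, so tests over them describe these 2 libraries.

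The comparison of the 2 libraries asked how far biological replicates found the same accessible chromatin. Promoters of all 18 neural progenitor genes were accessible in both libraries, among them Sox2 and Hes1, which maintain progenitors, and Pou3f3, a neural POU factor. The same held for all 18 genes of postmitotic neurons, such as Map2 and the splicing factor Rbfox3, and for all 15 cell cycle and all 16 housekeeping genes. Of 21851 protein-coding genes, 13701 had a promoter region in both libraries and 497 in only 1 of them. Several regulators were among the latter. Pax2, Pax7 and Wnt1 had a promoter region in library 2 only, as did the forebrain genes Fezf1, Fezf2 and Nkx2-1, whereas Corin and Barhl1 had one in library 1 only. Where these regions were also in the pooled list they were weak, with a fold enrichment of 2.67 at Pax2, 2.87 at Pax7 and 2.95 at Barhl1 against a median of 7.48 over all promoter regions.

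Of library 1's regions 77.3% overlapped a region of library 2, and of library 2's regions 79.8% overlapped a region of library 1, a mean of 78.5% ± 1.75 (SD, n = 2). Both percentages describe the overlap of the same pair of libraries, counted from each side, so their SD is not an error over independent replicates. Regions moved to random positions on the same chromosome overlapped in 3.12% of cases, with a range of 2.88% to 3.40% in 100 shifts. Of the regions in each library's IDR thresholded list, 99.3% overlapped the other library's larger pseudoreplicated list. The regions of 1 library alone were weaker than shared ones, with a median fold enrichment of 3.05 against 4.85 in library 1 and of 3.08 against 4.94 in library 2. Of these unshared regions, 70.0% in library 1 and 68.9% in library 2 overlapped a region of the list from pooled reads. The pooled reads include those of the same library, so this overlap is not independent. Only 1.34% of library 1's and 1.79% of library 2's unshared regions overlapped the other library's ranked list. The ranked lists were little larger than the pseudoreplicated ones, with 61864 regions in library 1 and 59440 in library 2. Across 44608 pairs of shared regions, the ranks of fold enrichment had a Spearman rho of 0.891, a description across regions and not across samples.

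Promoter regions were found again more often than distal ones. In library 1, 94.98% of 15137 promoter regions and 71.3% of 44593 distal regions were also in library 2. In library 2, 95.2% of 15084 promoter regions and 74.3% of 42658 distal regions were also in library 1. The difference was 22.3 percentage points ± 1.98 (SD, n = 2, again 1 pair of libraries counted from each side), and it was not tested across samples. Promoter regions were also stronger, and within deciles of fold enrichment the difference, as an unweighted mean over deciles, was 12.02 points.

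**Figure D1:**
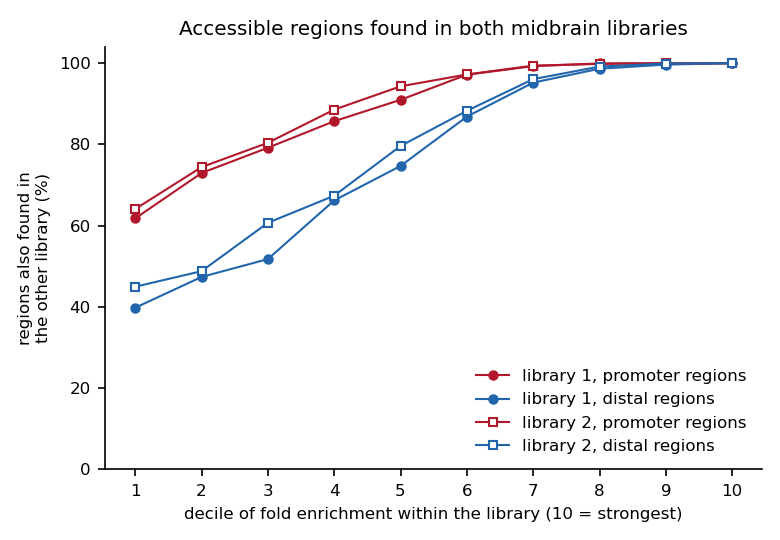
Percentage of each library's regions that overlap a region of the other library (vertical axis), by decile of fold enrichment within that library (horizontal axis), for promoter regions in red and distal regions in blue, with library 1 as filled circles and library 2 as open squares. In the weakest decile, 61.8% of promoter and 39.8% of distal regions of library 1 were shared, and in the strongest decile all were shared in both libraries.

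The next question was where in the genome the accessible regions lay. Promoters held 15930 regions, 19.9% of the 79912, against 2.76% after random shifts (range 2.52% to 2.98%), a 7.23-fold excess. Exons held 3.32% of regions against 2.37% after shifts, and introns 36.8% against 35.9%, the latter inside the shifted range of 34.7% to 37.4%. Intergenic sequence held 39.98% against 58.9%. These are shares of all regions, so the excess at promoters lowers the others. The intron share therefore does not show whether distal regions favoured introns. Shifted regions could also land in assembly gaps, which count as intergenic. A promoter region of the pooled list was present for 14398 genes, or 65.9%. Promoter regions had a median fold enrichment of 7.48 and a median width of 1197 bp, and the 63982 distal regions 3.25 and 501 bp. In the conservative list of peaks that passed the depositors' reproducibility threshold, the promoter share was 39.9%.

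The 10 genes with the most distal regions in the pooled list all had long territories, meaning sequence nearest to their starts, from 286 kb at Fyn to 751 kb at Nrxn3, and their ranking was not adjusted for this. In that list Bach2, a transcription repressor, had 44 within 100 kb of its starts and Ank3, an ankyrin of the axon initial segment, 43. The other 8 were Frmd4a with 41, Tiam1, a Rac exchange factor, with 39, the Notch coactivator Maml3 with 38, Ank2, Auts2 and the kinase Fyn with 37 each, Nckap5 with 35 and the synaptic neurexin Nrxn3 with 32. The order differed in single libraries, where Nrxn3 had the most, 33 and 32, against 26 and 30 for Bach2 and 20 and 17 for Nckap5 in libraries 1 and 2. The mean over all genes was 2.04 and the median 1. All 10 of these genes also had a promoter region in both libraries.

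The 10 regions with the highest fold enrichment were all intergenic and present in both libraries. The highest, at chrX:143482934-143483180 (mm10), 35531 bp from the nearest start, that of Pak3, reached 53.6. The next, at chr2:69355470-69355735 near Abcb11, reached 51.7, and chr2:3964425-3964690 near Frmd4a reached 42.8. The remaining 7 lay nearest to Gm5426, G6pd2, Galc, Gm13283, Tyrp1, 4930467E23Rik and Nxph1, with values down to 26.0. Of these 10 regions, 6 matched the mitochondrial genome at 90% identity or more over at least 100 bp.

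The promoters of 23 gene lists were compared with those of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Of the 23 lists 6 were higher than other genes, 4 of them neural and the others cell cycle and housekeeping. All 17 genes of glutamatergic midbrain neurons had a promoter region (adjusted exact p = 0.00417), including Ebf3, Tcf7l2 and Barhl2, against 65.9% of other genes. All 18 neural progenitor genes and all 18 genes of postmitotic neurons did as well (adjusted exact p = 0.0033 for each), as did all 15 cell cycle genes (0.00952) and all 16 housekeeping genes (0.00577). Of the GABAergic list, 14 of 15 genes had a promoter region (adjusted exact p = 0.0476), among them Lhx1, Ascl1 and the vesicular transporter Slc32a1, with Nkx2-2 as the exception. Against random lists matched on promoter CpG content, 5 of these 6 calls ended, with an adjusted permutation p of 0.249 for progenitors (13.05 points), 0.255 for housekeeping genes (11.98 points) and 1 for glutamatergic, GABAergic and cell cycle genes (5.17, 3.90 and 3.56 points). The middle 95% of matched lists reached 100%, the highest possible share, for each of these 5 lists. A list could not lie above that, so the lost calls alone do not show that CpG content accounts for them. In the matched lists 94.8% of genes had a promoter region for glutamatergic, 89.4% for GABAergic and 96.4% for cell cycle genes. The share was 87.0% for progenitors and 88.0% for housekeeping genes, against 65.9% of other genes. Matching on CpG content thus removed most of each difference from other genes.

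Lower than other genes were 7 lists, among them liver, germline, erythroid, epidermal and microglial genes. Of 15 liver genes 2 had a promoter region, Foxa3 and Trf (13.3%, exact 95% interval 1.66 to 40.5, adjusted p = 0.000316), and Afp and Ahsg had none. Of 14 germline and pluripotency genes 3 did (21.4%, adjusted exact p = 0.0033), with none at Ddx4 and Dppa3. The erythroid list had 4 of 15 (26.7%, adjusted exact p = 0.00577), including Gypa and Nfe2 but not Alas2 or Epb42. The epidermal list had 4 of 14 (28.6%, adjusted exact p = 0.0163), including Krt8, Epcam and Krt10. The microglial list had 5 of 14 (35.7%, adjusted exact p = 0.0446), including Irf8, Csf1r and C1qc but not Aif1 or C1qa. Of 1092 olfactory receptor genes 12 had a promoter region (1.10%, exact 95% interval 0.569 to 1.91), among them Olfr94 and Olfr658. Single libraries gave lower counts for some of these lists, with 4 and 7 olfactory receptors in libraries 1 and 2 and 2 in both, 1 and 2 germline genes, and 3 and 4 microglial genes. Against CpG-matched lists the liver (-23.8 points, adjusted permutation p = 0.249), epidermal (-14.4 points, 0.823), erythroid and microglial calls (1 for both) ended, and the erythroid and microglial differences turned positive, at 2.09 and 2.01 points.

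Hox genes, which pattern the body axis behind the midbrain, were also low, with 9 of 39 (23.1%, exact 95% interval 11.1 to 39.3, adjusted p = 6.3e-07). The count was 5 of 39 (12.8%) without replicate 2 and 1 of 39 (2.56%) in the conservative list, and the call was made in both. The Hoxa cluster at chr6:52155590-52260880 (mm10) held 3 regions in 105 kb and a promoter region at only 1 of its 11 genes, Hoxa1, and none of the 10 Hoxb genes had one in the pooled list. A region at chr6:52221277-52222464, chosen for mention after it was seen, lay over the outer 5' end of the Hoxa7 gene but over 1 kb from its protein-coding starts. The Hoxc cluster held 4 regions, with a promoter region at 3 of its 9 genes, Hoxc5, Hoxc10 and Hoxc13. The Hoxd cluster held more, 10 regions in 96.8 kb, with a promoter region at 5 of its 9 genes, Hoxd1, Hoxd8, Hoxd9, Hoxd12 and Hoxd13.

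No difference passed the test for 10 lists. They were midbrain patterning (14 of 18, adjusted p = 0.364), dopaminergic neurons (15 of 17, 0.101), oculomotor and cholinergic neurons (8 of 9, exact test, 0.23), and floor and roof plate (14 of 16, 0.148). The others were forebrain regulators (16 of 18, 0.0746), hindbrain and serotonergic regulators (10 of 12, 0.292), glia (9 of 15, 0.625), endothelial cells (7 of 14, 0.299), meningeal mesenchyme and pericytes (10 of 14, 0.784) and muscle (6 of 15, 0.0805). Without replicate 1, floor and roof plate genes passed as higher (adjusted exact p = 0.026) and muscle genes as lower (0.0419). Muscle genes also passed as lower in the conservative list (1 of 15, adjusted exact p = 0.000158) and the larger thresholded list (2 of 15, 0.000778), floor and roof plate genes as higher in the pooled pseudoreplicated list (0.0052), and forebrain regulators with the 2 kb window (0.02). In the conservative list the differences for forebrain regulators (8 of 18), oculomotor (3 of 9), midbrain patterning (9 of 18), dopaminergic (10 of 17) and meningeal genes (8 of 14) were negative, without passing, and those of forebrain, oculomotor and meningeal genes were negative in the larger thresholded list too (-21.2, -26.8 and -10.1 points). Against CpG-matched lists those for midbrain patterning (77.8% against 89.9%) and floor and roof plate (87.5% against 93.7%) also turned negative and that for glia (60.0% against 50.3%) positive, none passing the permutation test.

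Against the CpG-matched lists, 4 of the 13 calls were left. Genes of postmitotic neurons were higher (100% against 77.7%, permutation test, adjusted p = 0.0092). Hox genes (23.1% against 88.7%), germline genes (21.4% against 64.8%) and olfactory receptors (1.10% against 15.2%) were lower, each at an adjusted permutation p of 0.00153. The GABAergic call also ended in the conservative list (6.94 points, adjusted exact p = 0.912), in the larger thresholded list (19.9 points, 0.237) and with only the outermost start of each gene (23.5 points, 0.108), against 27.5 points in the main list.

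**Figure D2:**
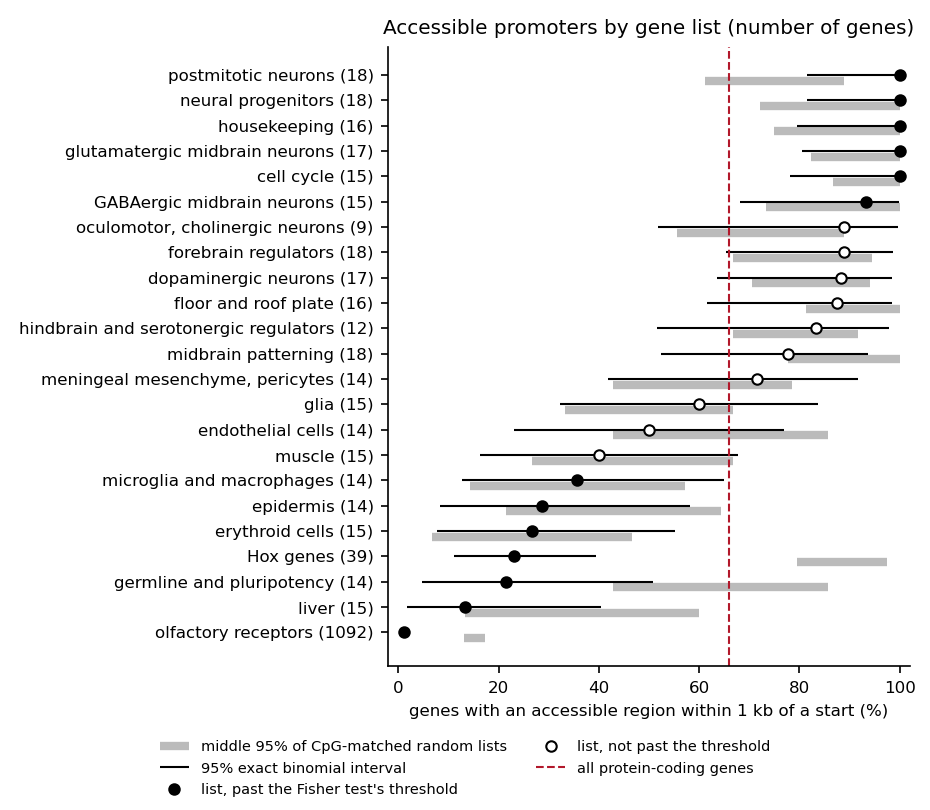
Percentage of genes in each of 23 lists with an accessible region within 1 kb of a start (horizontal axis; number of genes after each name), with the exact 95% binomial interval as a black line, the middle 95% of random lists matched on promoter CpG content as a grey bar, and the 65.9% of all protein-coding genes as a dashed line. Filled circles passed Fisher's exact test after adjustment, and the Hox genes, at 23.1%, lay far below their matched range of 79.5% to 97.4%.

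Landmark genes of the midbrain were read one by one. Otx2, required for midbrain identity, had a promoter region and 16 distal regions, the strongest at chr14:48709395-48710277 (mm10, intergenic, 36.2 kb from its start, fold enrichment 7.43). The isthmic genes En1 and En2 had 13 and 7 distal regions and a promoter region each. Pax2 had 16 distal regions, with 10 and 9 in libraries 1 and 2. Pax5 had no promoter region in the main list, yet an intronic region of Pax5 at chr4:44703749-44704941 reached a fold enrichment of 12.99, at percentile 99.5 of distal regions. Fgf8 and Wnt1, signals of the isthmus and dorsal midline, had 2 distal regions each and no promoter region in the main list. In each single library Fgf8 again had 2 distal regions and Wnt1 had 1. The strongest distal regions of Fgf8 and Wnt1 in the main list lay at chr19:45717498-45718701 (24.6 kb away, fold enrichment 9.35) and chr15:98797543-98798689 (8.31 kb away, 9.73), both intergenic.

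Among genes of dopaminergic development, Lmx1b had 22 distal regions, the strongest in its own intron at chr2:33615754-33617259 (fold enrichment 7.55). Foxa2, the floor plate regulator, had 15, the strongest at chr2:148114607-148115179, 67.8 kb from its start. Th, the rate-limiting enzyme of dopamine synthesis, had no promoter region and 5 distal regions, with an intronic one at chr7:142918735-142920041 at a fold enrichment of 5.57. Nr4a2 had a promoter region and 5 distal regions, and Pitx3 a promoter region of fold enrichment 2.17 in the pooled list that neither library alone held. For other lineages, Pou4f1 of glutamatergic neurons had 10 distal regions, with 6 and 8 in the libraries, and the GABAergic regulators Gata2 and Gata3 had 3 and 2, with 1 and 4 in library 1 and 1 and 2 in library 2. Foxg1, the forebrain regulator, and Egr2 of the hindbrain each had a promoter region in both libraries. Their distal counts were 1 and 5 in the pooled list, 1 and 2 in library 1 and 0 for both in library 2. The pooled distal region of Foxg1, at chr12:49374259-49374948, overlapped no region of either library's own list. Egr2's strongest pooled distal region, at chr10:67535561-67536441, overlapped a region in both libraries, although library 2 counted 0 distal regions for Egr2.

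**Figure D3:**
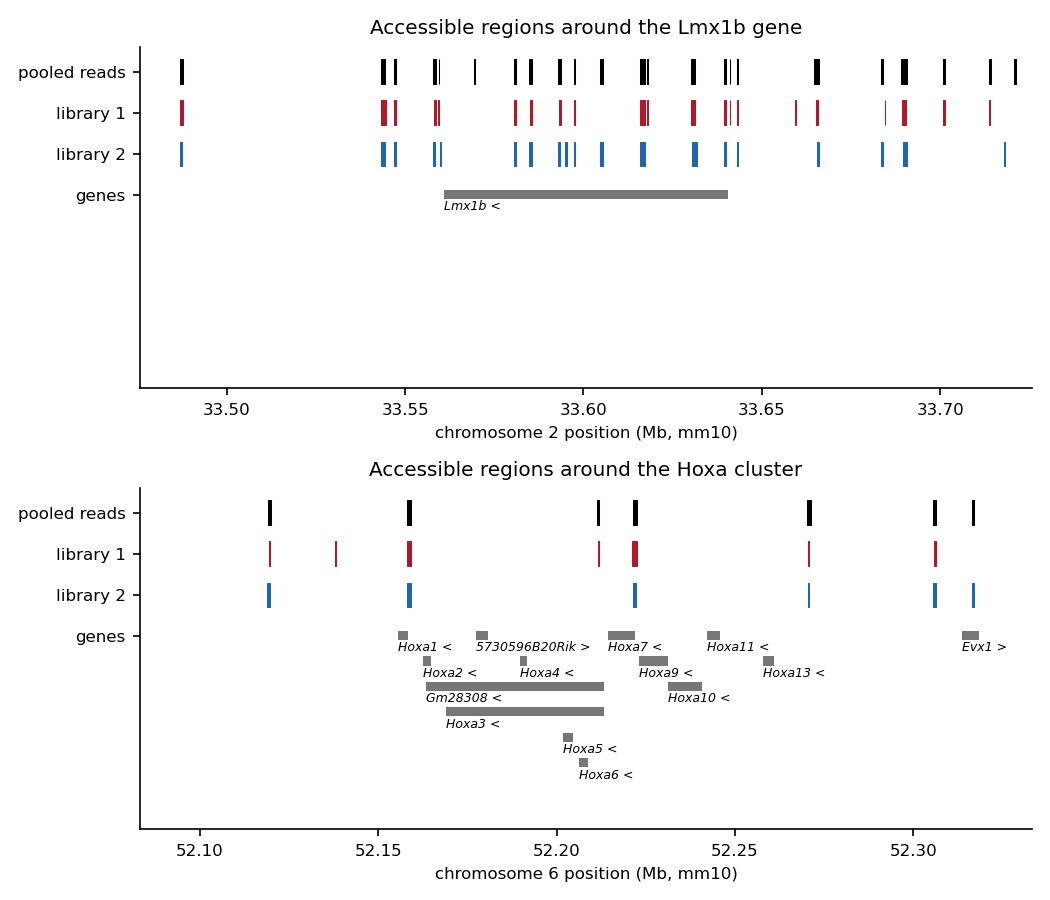
Accessible regions as vertical bars in 250 kb around the Lmx1b gene and around the Hoxa cluster (horizontal axis, mm10 position in Mb), in the list from pooled reads and in each library's own list, with protein-coding genes drawn below and their direction marked by an arrowhead. The pooled list held 25 regions in the Lmx1b span and 8 in the Hoxa span.

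Distal regions were then compared between the lists and random lists of genes with matched territory, the sequence nearest to a gene's starts. Matching was on the decile of territory length, so differences within a decile remained, here and in the later comparisons of distal regions. Within the same decile, for instance, Ptch1 had 164 kb, Map2 333 kb and Tcf7l2 349 kb. Midbrain patterning genes had the largest excess, with 11.4 distal regions per gene against 4.09 in matched lists, a ratio of 2.80. Pax7, a dorsal midbrain factor, had 23, Lmx1b 22, Meis1 19 and Otx1 17. Single libraries mostly held fewer, and the numbers in brackets after a gene are its counts in libraries 1 and 2, here Pax7 (13 and 15), Lmx1b (18 and 19), Meis1 (16 and 12) and Otx1 (11 and 11). Genes of glutamatergic midbrain neurons had 9.59 against 4.36 (ratio 2.20), with 21 at Ebf3 (13 and 17), 19 at Tcf7l2 (16 and 15) and 14 at Barhl2 (8 and 13). For both lists, as for the olfactory receptors, the two-sided permutation p was 0.0002, the smallest that 10000 lists can give, and 0.00153 after adjustment over 23 lists. Neural progenitor genes had 8.50 against 4.06 (ratio 2.09, adjusted permutation p = 0.0046), with 19 at Sox2 (12 and 13), 18 at Hes1 (12 and 11) and 15 at Pou3f3 (11 and 13).

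Genes of postmitotic neurons had 8.78 against 4.79 (ratio 1.83, adjusted permutation p = 0.0138), with 23 at Rbfox3 (18 and 18), 18 at Map2 (12 and 16) and 17 at Celf4 (7 and 7). Glial genes had 5.33 against 2.19 (ratio 2.44, adjusted permutation p = 0.00736), with 15 at the myelin gene Mbp (14 and 14), 10 each at Olig2 (6 and 8) and Aqp4 (7 and 8), and 9 at Pdgfra (4 and 3). Cspg4, Gfap, Mag, Mog and Plp1 had no promoter region in the pooled list or in either library. Dopaminergic genes had 6.82 against 3.94 (ratio 1.73) and GABAergic genes 6.60 against 3.62 (ratio 1.83), both at an adjusted permutation p of 0.0483. Olfactory receptors had 0.136 against 0.712 (ratio 0.190). All 8 of these calls were also made from each library's own list.

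The other 15 lists did not pass. Among them were floor and roof plate (6.63 against 3.86, adjusted permutation p = 0.0603), with 16 at Ptch1 (10 and 10), 15 at Foxa2 (9 and 11) and 12 at Msx1 (6 and 8), and forebrain regulators (4.89 against 3.02, 0.0764), with 10 each at Dlx2 (8 and 6) and Fezf1 (6 and 5) and 9 each at Emx1 (6 and 5) and Emx2 (8 and 8). Hindbrain and serotonergic regulators (6.08 against 3.67, 0.122) had 12 at Lhx4 (10 and 5) and 11 at Atoh1 (6 and 8). With assignment within 50 kb these 3 lists passed (adjusted permutation p = 0.00092, 0.0309 and 0.0102). Floor and roof plate and forebrain lists also passed with unmerged peaks (permutation, 0.0253 and 0.0396), and forebrain regulators without replicate 2 (0.0197) and in the pooled pseudoreplicated list (0.0448). Hox genes had 0.436 against 0.532 (0.871). Oculomotor genes had 2.56 against 2.96, endothelial genes 3.36 against 3.55, meningeal and pericyte genes 2.71 against 3.66, and microglial genes 1.71 against 1.35. Muscle genes had 2.40 against 1.69, liver genes 0.867 against 1.32, epidermal genes 1.43 against 1.71, germline genes 1.57 against 1.61 and erythroid genes 0.533 against 0.822. Housekeeping genes had 2.06 against 1.23 and cell cycle genes 1.33 against 1.24. In these 11 lists the adjusted permutation p ran from 0.32 to 0.999.

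Without its top gene, Lmx1b, the dopaminergic list had a ratio of 1.55 and an unadjusted permutation p of 0.066, and the GABAergic list without Lhx1 a ratio of 1.67 and a p of 0.045. The dopaminergic call ended with assignment within 500 kb (ratio 1.63, adjusted permutation p = 0.106), in the conservative list (1.82, 0.0943) and in the larger thresholded list (1.53, 0.283), against a ratio of 1.73 in the main list. The GABAergic and glial calls ended at 500 kb (ratios 1.70 and 2.06, adjusted permutation p = 0.106 and 0.0705). That of postmitotic neurons ended in the conservative list (ratio 1.84, permutation, 0.0808) and the larger thresholded list (1.88, 0.0565), at ratios close to the 1.83 of the main list.

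**Figure D4:**
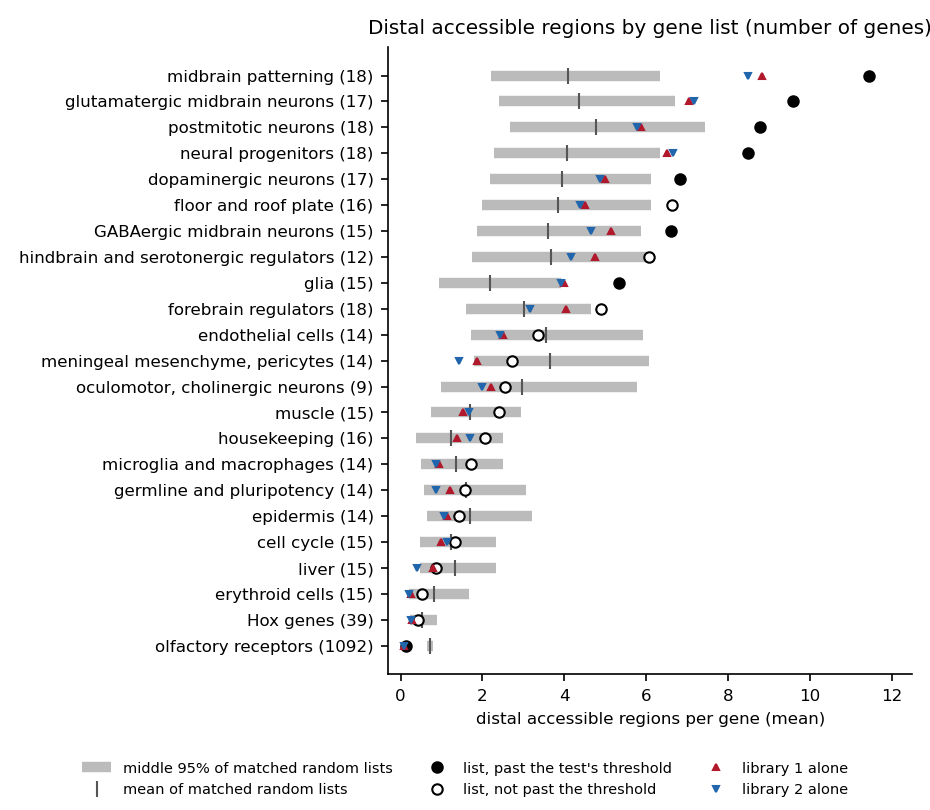
Mean number of distal accessible regions per gene in each of 23 lists (horizontal axis; number of genes after each name), in the pooled list as circles and in each library alone as triangles, with the middle 95% of 10000 matched random lists as a grey bar. Filled circles passed the permutation test after adjustment, from 11.4 regions per midbrain patterning gene down to 0.136 per olfactory receptor gene.

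Known sequence patterns of transcription factors, 21 in all, were counted within 100 bp of the summits of the 63982 distal regions and in flanks centred 500 bp away. The pattern of CTCF, the insulator protein, had the highest ratio of summit to flank density, 14.0 against at most 5.96 for 50 letter permutations of the same pattern. It occurred at the summits of 4.07% of distal regions and in the flanks of 0.274%. The pattern of RFX factors, regulators of ciliary genes, reached 10.7 against at most 10.2, and with windows of 50 bp it stood above CTCF (17.6 against 17.1). The proneural E-box CAGCTG reached 2.19 against at most 2.02, the POU pattern ATGCAAAT 1.58 against at most 1.38, and the SP and KLF pattern GGGCGG 2.76 against at most 2.62. These 5 patterns exceeded all their permutations and passed Fisher's exact test of regions with a match, with an adjusted p of 1.95e-108 for RFX and 5.25e-28 for POU. With flanks 1 kb away the CAGCTG call ended, at 2.33 against a permutation at 2.37. GGGCGG has only 5 distinct permutations, which limits that comparison.

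Patterns of other midbrain factors did not meet both criteria. CAGATG and the SOX pattern ACAATGG each reached 1.35 with permutations up to 1.47 and 1.45, and the OTX pattern TAATCC 1.04 with permutations up to 1.32. The homeodomain pattern TAATTA lay at 0.876, below the flank density although above all 13 of its permutations, the highest at 0.724. The Fisher criterion compared summits with flanks without regard to letter composition. The median ratio of the permutations was 0.416 for TAATTA but 2.34 for GGGCGG. Failing that criterion therefore does not show that TAATTA was no denser at summits than its letters alone would give. The GATA pattern lay at 0.776, MEF2 at 0.794 and the liver factor HNF4's at 0.663. The TEAD pattern lay at 1.01, the PU.1 pattern of microglia at 1.02, AP-1 at 1.13, EBF at 1.57, ETS at 1.78 and ZIC at 2.01. The patterns of NFI at 3.79, of NRF1 at 6.56 and of REST, the repressor of neuronal genes, at 2.58 were each exceeded by at least 1 of their permutations. At promoter regions in place of distal ones, 3 patterns met the criteria. RFX and SP and KLF were again among them, CTCF, CAGCTG and POU were not, and the ETS pattern was gained. Promoter regions had a median width of 1197 bp against 501 bp for distal regions. Flanks centred 500 bp away can therefore lie inside the same promoter region, so the flanks of promoter and distal regions are not alike.

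**Figure D5:**
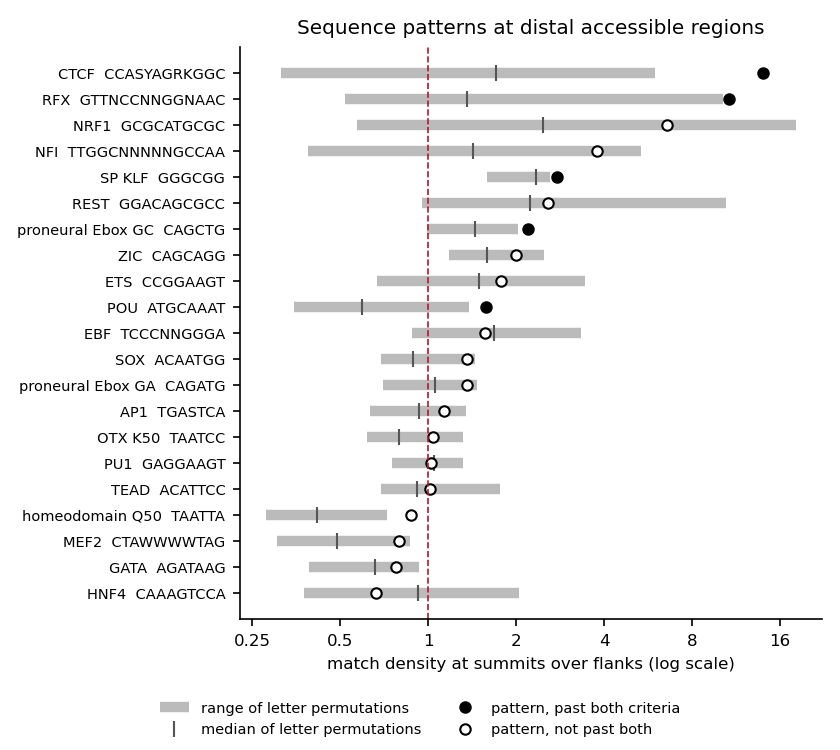
Density of matches at the summits of distal regions over that in flanks (horizontal axis, log scale) for 21 sequence patterns, with the range and median of up to 50 letter permutations of each pattern as a grey bar and tick. Filled circles mark the 5 patterns that met both criteria, with CTCF at 14.0 and RFX at 10.7.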

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

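The search of left-out peaks for mitochondrial sequence was chosen only after those peaks were seen. A signal lay in data outside the main measurement, in the ranked lists, which hold peaks that passed the IDR threshold and that the thresholded lists leave out. There were 326 such peaks beside the conservative list, 338 beside the larger pooled list, 250 in library 1 and 233 in library 2. Of the 326, 130 lay on contigs other than chromosomes 1 to 19, X and Y, and 196 lay on those chromosomes, in 78 intervals. The deposited file lists derive the thresholded lists from the alignments and 1 further file whose content they do not describe, and the ranked lists from the alignments alone. Of the 78 intervals, 1 matched the mitochondrial genome, at chr1:24611586-24616165 (mm10), with 99.96% identity over 4580 bp.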

How the results depend on the processing

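No test in this part was chosen only after its result was seen. Of 83 values of the results that answer a comparison, 57 stayed within a set margin and 26 moved. The margin was the spread of the libraries' values, or 1.5 times the main count for counts. For the rank correlation it was a 95% interval that treats region pairs as independent. The cause of the moves was not tested. The overlap of the libraries (78.5%) was 69.7% with 50% reciprocal overlap, 72.5% with summits within 100 bp, 85.2% in the IDR thresholded lists, 80.4% among the strongest 50000 regions and 86.2% with unmerged peaks. The rank correlation (0.891) was 0.924, 0.903 and 0.904 with IDR lists, reciprocal overlap and -log10 p. The difference between promoter and distal regions (22.3 points) was 26.9 with reciprocal overlap and 12.02 within signal deciles. The promoter share (19.9%) was 39.9% in the conservative list, 38.9% in the larger thresholded list, 18.9% in the pooled pseudoreplicated list, 25.3% to 26.1% in single libraries, 18.4% and 21.8% with windows of 500 bp and 2 kb, and 28.6% with unmerged peaks. Promoter calls fell from 13 to 4 against lists matched on CpG content, 1 higher and 3 lower, and ranged from 12 to 15 under the other alternatives. Against the CpG-matched lists the differences for erythroid, microglial and glial genes turned positive (2.09, 2.01 and 9.70 points) and those for midbrain patterning and floor and roof plate negative (-12.2 and -6.19), none passing. Distal calls went from 8 to 5 with assignment within 500 kb, 4 of them higher, and to 13 without matching on territory, 3 of them lower, and ranged from 6 to 11 otherwise. Motif calls went from 5 to 3 in promoter regions and were 4 with flanks 1 kb away, where CAGCTG was lost, and 5 under the others.

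Of 207 values for single lists, 174 kept their direction and their side of the threshold for promoters, with 10 weaker, 6 stronger, 2 reversed and 15 moved, and 167 for distal counts, with 7 weaker, 12 stronger and 21 moved. Among 216 values each for named genes, the promoter call was kept in 202 and the distal count in 46. Pax2 lost its promoter region in both thresholded lists and without replicate 2. Without replicate 1, floor and roof plate (adjusted exact p = 0.026) and muscle (0.0419) passed for promoters, and without replicate 2 forebrain regulators passed for distal regions (permutation, 0.0197). Depth is unknown, so its effect on these values was not measured.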

Other observations

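The tests of gene families, promoter strength, list pairs, mitochondrial matches, reads on the X chromosome and deciles of -log10 p were chosen only after the results were seen. Of 22 gene families, 5 had more distal regions than matched lists and 4 had fewer. Ephrins and their receptors, which guide axons, had 6.73 per gene against 3.25 in matched lists (adjusted permutation p = 0.0044), with 17 at Efna5. Semaphorins and plexins had 5.66 against 3.12 (0.00935), with 22 at Sema6a, LIM homeobox genes 8.50 against 3.94 (0.0088), Sox genes 7.32 against 3.79 (0.0132), with 20 at Sox5, and Fox genes 4.86 against 2.87 (0.00616), with 29 at Foxp1. GABA-A receptor genes were lower, at 1.37 against 3.56 (0.00935), as were cytochromes P450, at 0.871 against 2.10 (0.00147), vomeronasal receptors, at 0.177 against 1.86, and beta defensins, at 0.190 against 0.930. The Irx (7 against 5.91, 0.733), Zic (3.80 against 2.70, 0.582) and Pou families (6.13 against 3.85, 0.122) were among those that did not pass. Against lists matched on CpG content, promoters of semaphorins and plexins (96.6% against 79.7%) and of glutamate receptors (100% against 82.8%) were higher, and those of the protocadherin clusters (18.2% against 76.8%), keratins (12.2% against 49.5%), vomeronasal receptors and beta defensins were lower. All 22 ephrins and receptors had a promoter region, against 92.5% in the CpG-matched lists, which did not pass (adjusted permutation p = 0.398).

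Accessible promoters of developmental regulators, and of most other lists, were weak. Among genes with a promoter region, the mean percentile of fold enrichment was 15.4 for midbrain patterning genes against 53.0 in lists matched on CpG content, 14.4 against 50.3 for dopaminergic genes, 10.5 against 48.5 for forebrain regulators and 9.58 against 52.9 for Hox genes, each at an adjusted permutation p of 0.000475. Of 19 lists with at least 5 such genes, 16 were lower and none higher, and postmitotic neuron (37.8 against 47.8), cell cycle (62.5 against 54.9) and housekeeping genes (58.4 against 52.3) did not pass. The excess of distal regions over territory was larger for midbrain patterning genes than for forebrain regulators (7.34 against 1.86 per gene, adjusted permutation p = 0.00105) and hindbrain regulators (7.34 against 2.42, 0.00942). It was also larger for glutamatergic genes than for forebrain regulators (5.23 against 1.86, 0.00942). It was not shown to differ between progenitor and postmitotic genes or between dopaminergic and GABAergic genes (adjusted permutation p = 0.951 for both). These were 5 pairs.

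The strongest regions lay away from promoters. Of the 10 with the highest fold enrichment, 6 matched the mitochondrial genome, against at most 1 in 1000 random draws of 10 distal regions and 12 of all 63982 distal regions, so reads of mitochondrial DNA placed on nuclear copies are a candidate source. Of the other 4, 3 had another nuclear match, against 8 of 200 random distal regions, so reads shared with near-identical nuclear sequence may have raised these. The region near Frmd4a at chr2:3964425-3964690 (mm10) had neither and stays open. No biological explanation was tested, since the design has 1 group.

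Distal regions were sparser on the X chromosome, with 5.95 per Mb against 25.6 on the autosomes, whose range was 21.6 to 28.9. Fewer reads per accessible X site were tested 3 ways: high-CpG X promoters had a median fold enrichment of 10.5, above the matched autosomal range of 8.89 to 10.3, and a median -log10 p of 198, inside the range of 177 to 249. Fold enrichment is a ratio over the caller's background, which may fall with the reads, so its level cannot decide this. Both medians cover only promoters with a called region. The third test was chosen after the first and second, and in it the lower autosomal density of a single library was still 2.86 times the X density of the pooled list, although pooled -log10 p was 1.83 times that of library 1 and 1.84 times that of library 2, which argues against fewer reads as the whole cause. Repeat content and gene density were tested with matched windows of 1 Mb, where the autosomes kept 2.31 times the X density (14.9 against 6.44, lowest draw 12.51), so they may account for part of the 4.30-fold difference only. Mappability of X sequence was not tested, nor was any biological explanation.

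Promoter regions were shared between libraries more often than distal ones by 22.3 points. Within deciles of -log10 p the difference was 6.17 points (6.82 and 5.52, the same pair of libraries counted from each side), as an unweighted mean over deciles. Stronger signal at promoters may account for part of it. Within cells of -log10 p and width together, as an unweighted mean over cells, it was 4.57 points (4.94 and 4.20). A difference left within cells argues against stronger and wider regions as the whole cause. The size of such means depends on the weighting. In library 1 the strongest decile of fold enrichment held 4905 of the promoter regions, with a difference of 0 points. The question stays open, and no biological explanation was tested.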
